A study of Homo sapiens with 4 samples.

How the data were processed

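Messenger RNA from 4 cultures of primary human epidermal keratinocytes was measured, 1 library per group: a non-targeting control siRNA and siRNAs against IRX2, IRX4 and IRX5. Per the labels' protocols, pooled siRNAs were transfected at 30 nM into semi-confluent monolayers, calcium at 1.8 mM was added 12 h later and RNA was collected 72 h after transfection. The labels' protocols name both a SMARTER and a TruSeq library kit and single-end sequencing on an Illumina HiSeq instrument, and which kit made these libraries is not given in the sources used here. Whether the cultures came from 1 donor or several is not given either.

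The deposited values are counts per Ensembl gene, whole numbers that are not normalized, in 1 column per library. Per the submitters' processing notes, Bowtie2, DESeq2 and the genome build hg38 were used, with no version, order or role. The counter, the annotation and the strand setting are not given in the sources used here, so reads from overlapping or antisense genes, and reads shared by near-identical copies, cannot be separated. The table held 35570 genes, of which 6195 had no symbol and 6147 of those were named from a reference table of gene identifiers; genes without a symbol in the deposited table took 0.732% to 0.819% of the counts. At least 1 count was found for 20160 genes.

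Total counts were 18493780 in the control, 21222434 in siIRX2, 40666539 in siIRX4 and 16022307 in siIRX5, a 2.54-fold range, and a count of 0 allows up to 0.162, 0.140, 0.0739 and 0.189 CPM (3 counts). Mitochondrially encoded genes took 4.04%, 4.00%, 5.08% and 3.81% of the counts, ribosomal protein genes 2.97%, 2.76%, 2.87% and 2.47%, and the 10 most abundant genes 7.06%, 6.92%, 6.76% and 6.95%.

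CPM values were computed on library sizes scaled by the trimmed mean of M-values (TMM, edgeR 4.0.16 in R 4.3.3), with factors of 1.00309, 1.00667, 0.998783 and 0.991522. Log2 ratios used a prior count of 2. The exact conditional (Clopper-Pearson) 95% interval of each ratio came from the counts of the compared libraries without the prior count and covers counting error only. With 1 library per group there are no residual degrees of freedom, so no test across genes was run and no p-value is given. A gene counted as 2-fold higher or lower when its log2 ratio was at least 1 in size, its interval excluded equality and its mean over the 4 libraries was at least 2 CPM, which 12427 genes reached. Distances between libraries used genes with a mean of at least 10 CPM.

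Gene lists were fixed before the data were examined: DNA repair (homologous recombination and Fanconi, end joining, base, nucleotide and mismatch repair, damage checkpoint), p53 targets, replication, mitosis, replication-dependent histones, keratinocyte states (basal, spinous, late, wound), hair follicle stem cell, signalling (Notch, Wnt, BMP and FGF components, TGF-beta response, immediate early), interferon and inflammatory genes, stress (unfolded protein response, amino acid stress, heat shock, NRF2 targets, hypoxia), lipid synthesis, oxidative phosphorylation, ribosomal proteins, ribosome biogenesis, housekeeping, the IRX family and markers of other cell types. A list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and it stood apart below percentile 2.5 or above 97.5. The random lists hold unrelated genes, whereas members of one list can move together between single libraries, so the percentiles describe these libraries and do not give how many lists would stand apart by chance. Lists with fewer than 5 measured members have values of their members only.

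Genes were named by a rule fixed before the data were examined: in each comparison the 10 highest and 10 lowest log2 ratios among 2-fold genes with a mean of at least 5 CPM, the IRX genes, up to 3 members of each list standing apart whose interval excluded equality, the 5 genes set furthest apart in each library and direction, up to 8 genes shared by all knockdowns, and the fixed genes BRCA1, BRCA2, CDKN1A, FGF18, KRT5, KRT14, KRT1, KRT10, IVL and MKI67. Some genes that the rule names are not reported here. Genes so named in 1 comparison were also given in others. Values are uncertain for named genes whose exons overlap another gene with over 10% of their counts: CDC25C, CDCA3, CMPK2, CCNE2, CRELD2, DDIT3, DNAJB9, FEN1, GINS2, KRT10, LOX, LOXL2, MRTO4, NID2, RAD54L, RPA3 and TAGLN.

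Because all comparisons share the control library, correlations and overlaps were set beside 20 simulated sets of unchanged libraries, drawn with Poisson noise alone or with an added log-normal spread between libraries. Gene positions, GC content and transcript length came from GENCODE 29. The calculations were tested on data simulated with Poisson noise alone, with known fold differences in 50 genes per size. Genes made 2.5-fold different were recovered in 98% (siIRX2), 96% (siIRX4) and 96% (siIRX5) of cases among about 12450 genes run. Genes made 1.5-fold different, below the 2-fold rule, were recovered in 0%. Of unchanged lists of random genes, 4.5%, 5.5% and 5% fell outside the percentile limits. These simulations held no spread between cultures, so they check the calculations only. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

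Alternatives were total-count, median-of-ratios (DESeq2 1.42.0) and upper-quartile scaling, prior counts of 0.5 and 5, no expression filter or a mean of at least 20 CPM, thinning to the shallowest depth, leaving out mitochondrial genes, thresholds of 1.5-fold and 3-fold, no condition on the interval, other reference libraries, and other ways to summarise and match lists. Removing the lowess trend (span 0.3) on GC content and transcript length, and leaving out cell cycle and repair lists, were added after the data were seen. Sex-linked marker genes were left out of the named genes.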

Results

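Messenger RNA was counted in primary human epidermal keratinocytes, the cells that form the outer layer of the skin, 72 h after transfection with pooled small interfering RNAs (siRNAs) at 30 nM. The siRNAs targeted IRX2, IRX4 or IRX5, which encode Iroquois homeobox transcription factors, and a non-targeting siRNA served as the negative control. There was 1 library in each of the 4 groups, so no difference below has a replicate check and none carries a p-value. The libraries held 18493780 (control), 21222434 (siIRX2), 40666539 (siIRX4) and 16022307 (siIRX5) counts. The labels describe the cells as proliferating, while the protocol in the same labels adds 1.8 mM calcium, which induces keratinocyte differentiation, 12 h after transfection. Of the differentiation transcripts, LORICRIN had 0, 0, 8 and 1 counts in control, siIRX2, siIRX4 and siIRX5, and KRT1 stood at 1.35, 1.92, 0.763 and 3.08 CPM (counts per 1e6 counts of the scaled library). Involucrin, IVL, stood at 403, 340, 247 and 388 CPM, and FLG at 20.3, 32.2, 19.2 and 17.9 CPM. KRT5, a keratin of basal keratinocytes, stood at 12110 CPM in the control. Ratios are given as log2 of a knockdown library over the control library, and the ranges beside them are 95% counting intervals, which cover counting error only and not the spread between cultures.

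Each targeted transcript was lowest in the library of its own siRNA. IRX2 (chromosome 5, 2745845 to 2751662, hg38) was at 65.0% of the control level in siIRX2 (interval 56.1% to 75.3%), with 15.2 CPM against 23.4 CPM. IRX4, on the same chromosome at 1877413 to 1887236, was at 45.3% of control in siIRX4 (41.3% to 49.8%), with 22.0 against 48.5 CPM. IRX5 (chromosome 16, 54930862 to 54934485) was at 29.4% of control in siIRX5 (20.1% to 42.0%), from 155 counts in the control and 39 in siIRX5. On the log2 scale the reductions were -0.62, -1.14 and -1.73, so IRX2 did not reach a 2-fold difference in its own knockdown. IRX4 in siIRX4 was at -0.99, just short of 2-fold, with the trend of ratios on GC content and transcript length removed. The siRNAs' positions on the transcripts are not given in the sources used here, and the counts cover whole genes.

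Other IRX transcripts differed from the control as well. IRX2 was at 123% of control in siIRX4 (110% to 138%) and 120% in siIRX5 (105% to 137%), and IRX4 was at 103% in siIRX2 and 85.6% in siIRX5 (77.3% to 94.8%). The log2 ratio of IRX4 in siIRX5 turned from -0.22 to 0.21 with the trend of ratios on GC content and transcript length removed, and to 0.14 and 0.33 against the other 3 libraries and the other knockdowns, references that include the siIRX4 library. IRX5 was at 79.6% of control in siIRX4 (65.1% to 97.6%) and 91.9% in siIRX2, the latter with an interval that included equality (73.3% to 115%). Against references that include siIRX5, the log2 ratio of IRX5 in siIRX4 turned from -0.33 to 0.29 and 0.60. IRX3 was at 80.8% in siIRX2 and 75.9% in siIRX4, IRX1 was at 152% in siIRX2 (109% to 215%), 135% in siIRX4 (99.1% to 185%) and 65.6% in siIRX5 (41.1% to 103%, from 32 counts against 57), and IRX6 had 0 counts in every library, which allows up to 0.189 CPM in the shallowest. The 5 measured members of the IRX family list had medians of -0.12, -0.33 and -0.22 in siIRX2, siIRX4 and siIRX5.

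**Figure D1:**
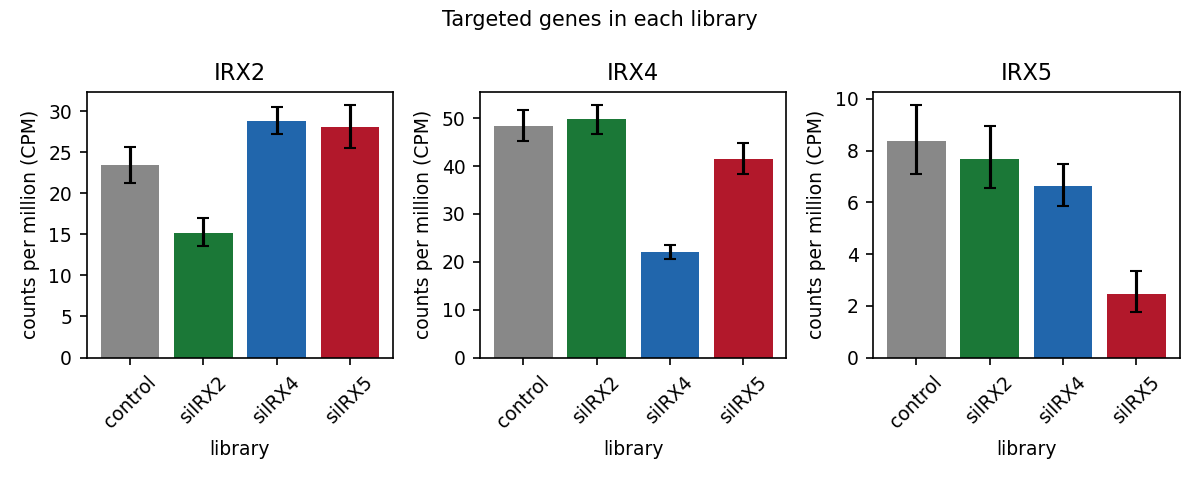
Expression of IRX2, IRX4 and IRX5 in CPM in the 4 libraries, with bars from 0 and 95% exact Poisson intervals for counting error only. Each gene was lowest in the library of its own siRNA, at 15.2, 22.0 and 2.45 CPM.

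The comparison of siIRX2 with the control asked which transcripts differed when IRX2 was targeted. Cell division genes were lower in siIRX2: 72 of the 73 measured genes of the G2/M and mitosis list lay below the control, with a median log2 ratio of -0.98 (-0.34 with the other knockdowns as reference), and 35 of them were at least 2-fold lower. Genes of the amino acid and integrated stress response were also lower, with a median of -0.51 over 40 members (-0.16 with the other knockdowns as reference), while interferon response genes were higher, with a median of 0.37 over 49 members (0.11 in that reference). Among single genes with a mean of at least 5 CPM, DISP2, which encodes a relative of the Hedgehog-releasing protein Dispatched, was highest, with 29.7 against 6.63 CPM (log2 2.15, 1.88 to 2.45). CORO1A, which encodes an actin-binding coronin, was lowest, with 3.93 against 16.8 CPM (log2 -2.07, -2.46 to -1.74). In all, 81 of 12427 genes were at least 2-fold higher and 224 at least 2-fold lower with an interval that excluded equality.

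Within the mitosis list, NDC80, a kinetochore subunit, stood at -1.44, the kinesin KIF14 at -1.63, the centromere protein gene CENPI at -1.37 and the proliferation marker MKI67 at -0.91. The DNA replication and G1/S list had a median of -0.57 (-0.16 against the other knockdowns), with 3 of 54 members 2-fold lower, among them the transcription factor E2F2 (-1.25) and the replicative helicase subunits CDC45 (-1.04, and 0.0422 against the other knockdowns) and GINS2 (-1.02). Homologous recombination and Fanconi genes had a median of -0.41 (-0.24 against the other knockdowns), with 7 of 50 members 2-fold lower. HROB was at -1.53 and RAD54L at -1.40, while BRCA1 and BRCA2 were at -0.55 and -0.52. The damage checkpoint list had a median of -0.23 over 25 genes, with the mitosis-promoting phosphatase genes CDC25C at -1.78 and CDC25B at -0.95. Base, nucleotide and mismatch repair genes had a median of -0.16, with CETN2 at -0.92, RPA3 at -0.73 and LIG1 at -0.68. End joining genes had a median of -0.05 and did not stand apart from random lists. The p53 target list was higher, with a median of 0.18, and its members included RRM2B (0.81), the p53 ubiquitin ligase gene MDM2 (0.69), SESN1 (0.68) and the cell cycle inhibitor gene CDKN1A (0.67, 0.64 to 0.70).

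Among stress and metabolic lists in siIRX2, 7 of 40 amino acid stress genes were 2-fold lower, including CHAC1 (-1.32), the cystathionine lyase gene CTH (-1.31) and STC2 (-1.26). The unfolded protein response list had a median of -0.25 (-0.14 against the other knockdowns), with the transcription factor XBP1 at -0.83. Hypoxia and glycolysis genes had a median of -0.17, with the glucose transporter gene SLC2A3 at -1.16. Medians were -0.11 for nuclear oxidative phosphorylation genes and -0.10 for cytosolic ribosomal proteins, of which RPL15 and RPS27A were each at -0.81. The housekeeping list, which did not stand apart, was as low, with a median of -0.12 and 15 of 19 members below the control. Inflammatory genes moved apart: the list median was -0.22 with ICAM1 at -1.27 and TNFAIP2 at -1.16, and 5 of 33 members were 2-fold higher, among them the neutrophil chemoattractants CXCL5 (1.72) and CXCL3 (1.58). Of the interferon list, 2 of 49 members were 2-fold higher and 2 were 2-fold lower, and IFI44L, MX2 and HERC5 stood at 1.18, 1.09 and 0.99.

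Among keratinocyte lists in siIRX2, spinous differentiation genes had a median of -0.19, with LY6D at -1.88 and KRT4 at -1.38 (0.36 against the other knockdowns). The late differentiation list did not stand apart (median 0.01), with 6 of 36 measured members 2-fold higher and 1 lower, among the higher ones the cornified envelope genes LCE3D (1.63), KPRP (1.80) and SPRR2G, which was at 4.12 against 0.97 CPM. Wound and stress keratinocyte genes had a median of -0.15, with MMP9 at -1.63, S100A8 at -1.70 and S100A9 at -1.03, and against the other knockdowns S100A8 turned to 0.29 and S100A9 was at -0.36. Notch, Wnt, BMP and FGF components had a median of -0.15, with WNT10A at -1.57, FGFBP1 at -1.04 and ID1 at -1.04. TGF-beta response and matrix genes had a median of 0.11 and went both ways, with 22 of 36 members above the control, CCN2 at 1.20 as the 1 member 2-fold higher, and LOXL2 (-1.81) and MMP2 (-1.47) 2-fold lower. Of the 4 measured fibroblast markers, TWIST2 was at -1.27 (-1.72 to -0.87), FBLN1 at -1.16 (-1.30 to -1.03), LOX at -0.95 (-1.75 to -0.27) and COL1A1 at 0.13 (-0.10 to 0.37), and the mesenchymal cadherin gene CDH11 was at -1.99. The basal keratinocyte list did not stand apart (median 0.01), with KRT5 at 0.01 and KRT14 at -0.09 (0.0790 with the GC and length trend removed). Of the 30 lists measured, 3 stood apart as higher and 14 as lower. The TGF-beta call lay near the limit, at percentile 97.94, the inflammatory and the Notch, Wnt, BMP and FGF lists no longer stood apart with the trend of ratios on GC content and transcript length removed, and with a mean of at least 20 CPM the checkpoint and hypoxia lists lost their calls while the homologous recombination median was -0.22 and still stood apart. When the other knockdowns replaced the control as reference, the wound list turned to 0.18 and stood apart as higher, at percentile 99.98, and the base, nucleotide and mismatch repair (0.0477) and ribosomal protein (0.0432) lists turned to small values above 0, while the oxidative phosphorylation (-0.00073) and hypoxia (-0.08) lists no longer stood apart.

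The comparison of siIRX4 with the control asked the same of IRX4. All 73 measured G2/M and mitosis genes were lower in siIRX4, with a median of -1.63, and 61 were at least 2-fold lower. The DNA replication and G1/S list had a median of -1.10, with 29 of 54 members 2-fold lower. MYCN, a MYC family transcription factor gene (chromosome 2, 15940564 to 15947007), had 4 counts in siIRX4 and 98 in the shallower control (log2 -4.89, -7.65 to -4.34). GABRP, a GABA receptor subunit gene, was at 1.43 against 31.8 CPM (-4.40, -4.89 to -4.08), and KRT4, a keratin of stratified mucosal epithelia, at 12.8 against 160 CPM (-3.64, -3.79 to -3.52). Among genes with a mean of at least 5 CPM, the highest ratio was that of ESM1, which encodes the secreted proteoglycan endocan, at 53.8 against 15.4 CPM (1.80, 1.62 to 1.99). In all, 88 genes were at least 2-fold higher and 269 at least 2-fold lower, and 113 of those 269 belonged to the replication, mitosis, recombination or checkpoint lists, where 4.37 were expected from the lists' size.

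The anaphase activator gene CDC20 was at -2.22 in siIRX4 (-2.35 to -2.09), with CENPM at -2.32, CDCA3 at -2.28 and MKI67 at -1.67. Of the replication genes, E2F2 was at -2.95, MCM10 at -2.04 and CDC45 at -2.02. Homologous recombination and Fanconi genes had a median of -0.48, which was -0.13 and no longer stood apart with a mean of at least 20 CPM. Of these, 17 of 50 members were 2-fold lower, including RAD54L (-2.11), BLM (-1.64) and BRCA2 (-1.14), and BRCA1 was at -0.98 (-1.15 to -0.82). Checkpoint genes had a median of -0.22, with CDC25C at -2.11, CLSPN at -1.49 and ATAD5 at -1.16. Base, nucleotide and mismatch repair genes had a median of -0.16, with NEIL3 at -1.84 and FEN1 at -0.87, and end joining genes had a median of -0.18, with PAXX at -0.66 and XRCC6 at -0.40. The p53 target list was higher at 0.29, with TP53INP1 and GDF15 each at 0.79, ZMAT3 at 0.76 and CDKN1A at 0.29.

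Differentiation genes were lower in siIRX4. The late differentiation list had a median of -0.50, with 5 of 36 members 2-fold lower, including KRT78 (-2.66), CST6 (-1.45) and CRCT1, which was at 16.7 against 67.2 CPM. IVL was at -0.71. In the spinous list the median was -0.28, with 7 of 34 members 2-fold lower, among them the desmosomal cadherin gene DSG1 (-2.11), KRTDAP (-1.67) and CALML5 (-1.36). Basal keratinocyte genes had a median of 0.12, with ASS1 at 0.63 and POSTN at 0.61, although KRT5 and KRT14 themselves were lower, at -0.64 and -0.45. Inflammatory genes were higher, with a median of 0.37, and included TSLP (1.65), CXCL6 (1.16) and CXCL2 (0.89), with 2 of 33 members 2-fold higher and 1 2-fold lower. Interferon response genes had a median of 0.14, with LAMP3 at 0.93, but a median of -0.29 against the other knockdowns, with 38 of 49 members below them. TGF-beta response genes had a median of 0.16, with TGFB2 at 0.86, 0 of 36 members 2-fold higher and 2 members 2-fold lower, LOXL2 (-1.13) and COL12A1 (-1.06). The fibroblast markers FBLN1 and LOX were at -0.95 and 0.95. Unfolded protein response genes had a median of 0.17, with the endoplasmic reticulum co-chaperone gene DNAJB9 at 1.21 and ERN1 at 0.71.

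Growth and metabolic lists were lower by small amounts in siIRX4. Ribosome biogenesis and MYC target genes had a median of -0.27, with 47 of 51 members below the control and LYAR at -0.74, SRM at -0.69 and MRTO4 at -0.61. Medians were -0.18 for oxidative phosphorylation (ATP5MC1 -0.52), -0.14 for hypoxia and glycolysis (ENO1 -0.59), -0.13 for cholesterol biosynthesis (LSS -0.56), -0.13 for fatty acid synthesis (DGAT2 -0.97) and -0.15 for housekeeping genes (GAPDH -0.48). The lists that did not stand apart in siIRX4 were replication-dependent histones (0.25), hair follicle stem cell (0.05), the IRX family (-0.33), wound and stress keratinocyte (-0.07), amino acid stress (0.07), heat shock (-0.05), immediate early (0.09), metallothioneins and NRF2 targets (0.12), ribosomal proteins (-0.03) and Notch, Wnt, BMP and FGF components (-0.03). In total, 6 of 30 lists stood apart as higher and 14 as lower. Restricting the genes to a mean of at least 20 CPM ended the call of the homologous recombination list (median -0.13), removing the GC and length trend ended those of the end joining, fatty acid and cholesterol lists, and with the mean of members 9 lists stood apart as lower, without the end joining, cholesterol, fatty acid, hypoxia and housekeeping lists. Against the other knockdowns in place of the control, the interferon median turned to -0.29 and the hypoxia median to 0.21, which stood apart as higher at percentile 99.85, while the cholesterol (-0.02), fatty acid (-0.07) and housekeeping (-0.10) lists no longer stood apart.

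The comparison of siIRX5 with the control concerned the gene that the series title links to DNA damage repair. Some stress lists were lower in siIRX5: the amino acid and integrated stress response list had a median of -0.79, with 14 of 40 members 2-fold lower, and the list of metallothioneins and NRF2 targets had a median of -0.66, with 9 of 28 members 2-fold lower. Heat shock genes were higher, with a median of 0.23, and the hypoxia and glycolysis list did not stand apart (median -0.12). Replication and mitosis genes were slightly higher, with medians of 0.23 and 0.36, and 69 of 73 mitosis genes lay above the control. COL5A3, a fibrillar collagen gene (chromosome 19, 9959561 to 10010471), was at 37.5 against 3.13 CPM (log2 3.55, from 596 counts against 58), and DSG1 (chromosome 18, 31318089 to 31357029) at 115 against 12.8 CPM (3.16, 2.97 to 3.37). The melanosomal and lysosomal glycoprotein gene GPNMB was at 31.8 against 494 CPM (-3.95, -4.09 to -3.83), and the acute-phase protein gene SAA1 at 7.36 against 162 CPM (-4.45, -4.74 to -4.20). In all, 205 genes were at least 2-fold higher and 543 at least 2-fold lower.

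Among the stress genes, the transcriptional regulator gene NUPR1 was at 4.09 against 47.1 CPM in siIRX5 (-3.50, -3.91 to -3.16), DDIT3, which encodes the stress transcription factor CHOP, at -2.90, and STC2 at -2.19. The DDIT3 gene overlaps the exons of MARS and MBD6, and reads of overlapping genes cannot be told apart because the counting strand is not given. Of the NRF2 list, the aldo-keto reductase genes AKR1C2 (-2.32) and AKR1C3 (-2.07) are closely similar copies whose reads can be shared, and the ferritin heavy chain gene FTH1 was at 368 against 1393 CPM (-1.92). Unfolded protein response genes had a median of -0.52, with 4 of 25 members 2-fold lower, including HERPUD1 (-1.63), CRELD2 (-1.33) and SDF2L1 (-1.15). The p53 target list did not stand apart (median -0.08), with CDKN1A at -0.11 (0.14 with the GC and length trend removed), although GDF15, which is also a stress-responsive cytokine gene, was at -3.18.

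Of the repair lists, homologous recombination and Fanconi genes stood apart in siIRX5, with a median of 0.27 and 38 of 50 members above the control. The list lost this call with genes restricted to a mean of at least 20 CPM. BARD1 was at 0.87 and FANCM at 0.80, but 0 members were 2-fold higher, and 1 was 2-fold lower, FANCE (-1.03). BRCA1 was at 0.55 (0.39 to 0.71) and BRCA2 at 0.62 (0.37 to 0.87). The homologous recombination list had the same sign as the mitosis list in each comparison. Its medians in siIRX2, siIRX4 and siIRX5 were -0.41, -0.48 and 0.27, and those of the mitosis list -0.98, -1.63 and 0.36. A difference in repair genes was therefore not separated from one in cell division genes. The checkpoint list had a median of 0.22, just inside the limits at percentile 97.275, end joining genes a median of 0.05, and base, nucleotide and mismatch repair genes a median of 0.01. FGF18, a growth factor of the hair follicle, had 2 counts in the control and 4 in siIRX5, so no difference was detectable at this depth. The hair follicle stem cell list did not stand apart in any comparison, with medians of -0.14, 0.05 and -0.14 in siIRX2, siIRX4 and siIRX5. Within the replication list, CCNE2 was at 1.56, E2F2 at 1.17 and RRM2 at 1.14, and within the mitosis list MAD2L1 was at 0.94 and CDK1 at 0.85.

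Several keratinocyte lists differed in siIRX5. Spinous genes had a median of 0.29, with 6 of 34 members 2-fold higher, including DSG1, the desmocollin gene DSC2 (1.71) and the epidermal transcription factor gene ZNF750 (1.34), while MAF (-2.33) and CEBPB (-1.36) were 2-fold lower and KRT10 was at -0.80. Late differentiation genes had a median of 0.28, with 4 of 36 members 2-fold higher, among them SPRR2E at 1.27 and KPRP at 1.14, with TCHH (-1.39) and ALOXE3 (-1.38) 2-fold lower, and IVL at -0.05 (0.21 with the GC and length trend removed). Wound and stress keratinocyte genes had a median of -0.35, with 7 of 29 members 2-fold lower, among them the antimicrobial protein genes S100A8 (-3.77), S100A7 (-2.62) and LCN2, which was at 239 against 1076 CPM (-2.17). Interferon response genes had a median of 0.31, with IFI44L at 1.05 and IFI44 at 1.02. This list alone stood apart as higher in every comparison with the control, with medians of 0.37 in siIRX2 and 0.14 in siIRX4. Against the other knockdowns its medians were 0.11 in siIRX2, -0.29 in siIRX4 and 0.10 in siIRX5. The comparisons share the same control library, so the common part cannot be assigned to any knockdown. The replication-dependent histone list had a median of -0.97 over 12 measured genes, all below the control, with H2AC8 at -2.35 and H4C8 at -1.48; histone genes are near-identical copies, so the assignment of their reads is uncertain. The histone list did not stand apart in siIRX2 (median 0.20) or siIRX4 (0.25), with 8 of 12 genes above the control in each. In every comparison its median had the opposite sign to those of the replication and mitosis lists. Only 12 of 46 listed histone genes were measured. Which library kit was used, and so how histone transcripts were captured, is not given in the sources used here. Medians were 0.26 for ribosome biogenesis (LYAR 0.77), 0.23 for heat shock (HSPA4L 1.56), -0.18 for ribosomal proteins (RPL13 -0.60), -0.26 for cholesterol biosynthesis (MVD -0.88) and -0.15 for TGF-beta response genes (TGFB2 -0.95), of which 2 were 2-fold higher and 2 were 2-fold lower. Of the 4 measured melanocyte markers, GPR143 was at -1.67 and QPCT at -0.53, and PMEL was at 0.65 and MITF at 0.71. In total, 8 of 30 lists stood apart as higher and 8 as lower. With genes restricted to a mean of at least 20 CPM, the replication list (0.19) and the homologous recombination list lost their calls in siIRX5, and the NRF2 median was -0.31 and still stood apart, at percentile 0.07. Against the other knockdowns the interferon (0.10), cholesterol (-0.15) and heat shock (0.22) lists no longer stood apart, and the TGF-beta list lost its call without the expression filter.

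**Figure D2:**
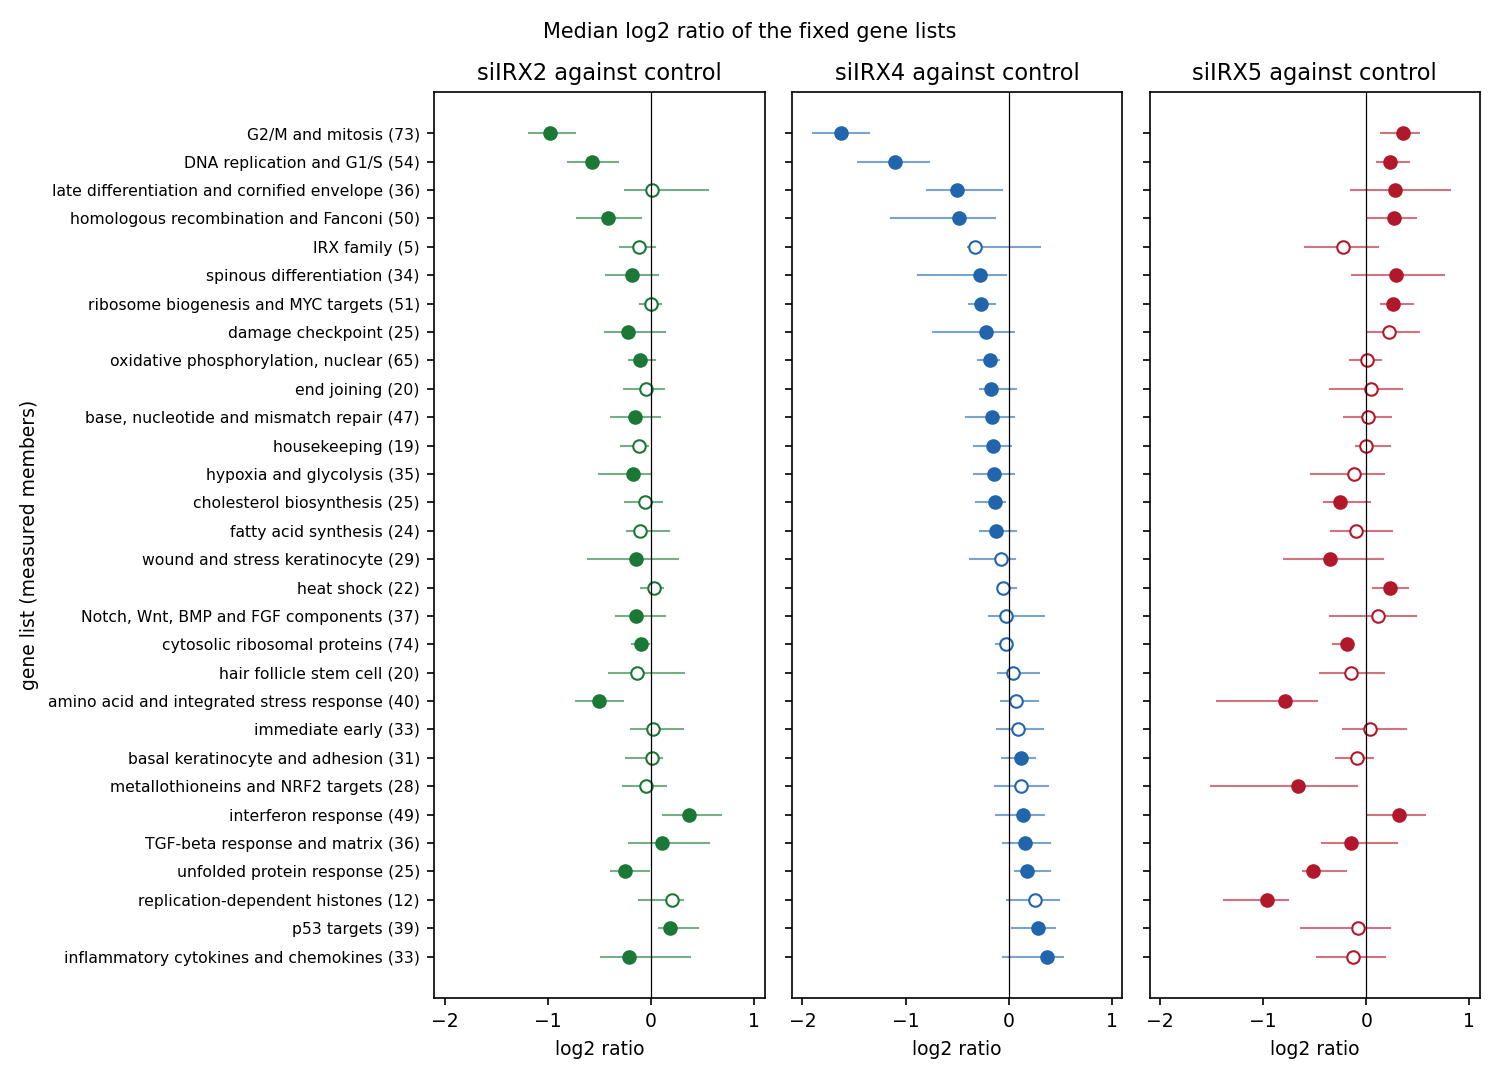
Median log2 ratio against the control of each gene list in siIRX2, siIRX4 and siIRX5, with lines from the lower to the upper quartile of its members and filled points for lists standing apart from 10000 random lists matched on expression. The G2/M and mitosis list lay at -0.98, -1.63 and 0.36.

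Set against each other, siIRX2 and siIRX4 shared lower cell division genes, while siIRX4 and siIRX5 differed in opposite directions for many of the same genes. Of the genes 2-fold lower in siIRX2 and of those in siIRX4, 80 were lower in both (4.85 expected from independent lists), and 46 of these 80 belonged to the replication, mitosis, recombination or checkpoint lists. In siIRX2 and siIRX5, 40 genes were lower in both (9.79 expected), 6 of which were amino acid stress genes. Genes higher in both numbered 11 for siIRX2 and siIRX4 (0.574 expected), 20 for siIRX2 and siIRX5 (1.34 expected) and 11 for siIRX4 and siIRX5 (1.45 expected). In siIRX4 and siIRX5, 4 genes were lower in both (11.8 expected), while 18 were lower in siIRX4 and higher in siIRX5 (4.44 expected) and 28 higher in siIRX4 and lower in siIRX5 (3.85 expected). DSG1 stood at -2.11 in siIRX4 and 3.16 in siIRX5, GABRP at -4.40 and 2.11, UPK1B at -2.07 and 1.91, and RGS2 at -1.62 and 1.94. The synaptic vesicle protein gene SV2B went the other way, at 1.21 in siIRX4 and -4.94 (-8.71 to -3.76) in siIRX5, where it had 2 counts, and ESM1 stood at 1.80 and -1.77.

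Across the 12427 genes, which are not independent replicates, the log2 ratios correlated with r = 0.456 for siIRX2 and siIRX4, 0.281 for siIRX2 and siIRX5 and -0.118 for siIRX4 and siIRX5. Unchanged libraries simulated with counting noise against the same control gave r = 0.608, 0.498 and 0.563, and covariances of 0.00829, 0.00831 and 0.00827 against the observed 0.0715, 0.0598 and -0.0267, which differ by 0.0632, 0.0515 and -0.0349. With a simulated spread between libraries of SD 0.298 on the log2 scale, an estimate from the knockdown pairs that includes their differences, the covariances were 0.0960, 0.0961 and 0.0966, and the differences -0.0245, -0.0363 and -0.123. That simulation shared 19.0, 16.9 and 18.2 lower genes and 22.8, 22.3 and 21.6 higher genes per pair, more than the higher genes observed in each pair, and part of any excess may come from the 1 control library, which cannot be split. Correlations that share no library were also computed. For siIRX4 against control with siIRX2 against siIRX5, r was 0.416. It was 0.378 for siIRX5 against control with siIRX2 against siIRX4, and 0.0419 for siIRX2 against control with siIRX4 against siIRX5. Without the expression filter, r of siIRX4 and siIRX5 turned to 0.21.

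**Figure D3:**
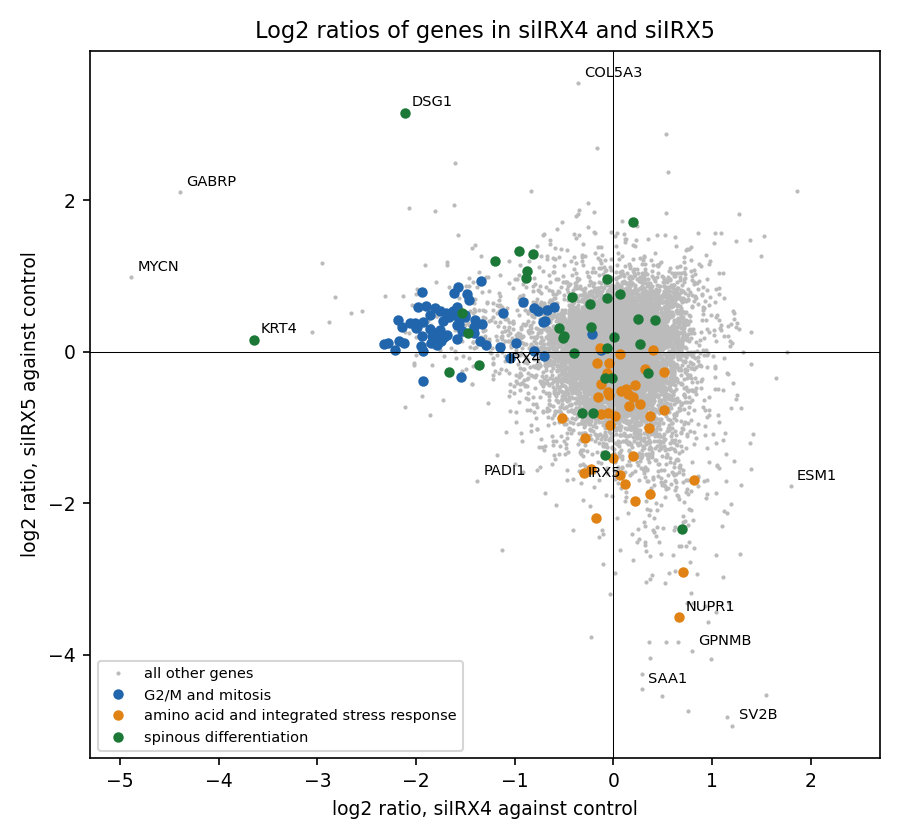
Log2 ratio against the control of each gene past the expression filter in siIRX4 (horizontal axis) and siIRX5 (vertical axis), with members of 3 gene lists in colour. Mitosis genes lay to the left of 0 and mostly above it, and DSG1 lay at -2.11 and 3.16.

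Genes set apart in 1 library, at least 2-fold beyond all other libraries, were most frequent in siIRX5, with 87 above and 309 below. The siIRX4 library had 19 above and 62 below, siIRX2 had 15 above and 35 below, and the control had 3 above and 1 below. These counts were not computed with the GC and length trend removed. The trend with GC content was strongest in siIRX5 (r -0.353 across genes). In siIRX2, the matrix protein gene THBS2 was at 377 CPM against 134 to 162 CPM elsewhere, and FBN1, which encodes fibrillin, was among the genes below. MYCN, GABRP, KRT78 and NID2 were below in siIRX4, and ESM1, TNFSF15 and CREBRF above. The siIRX5 library stood above the others for COL5A3, DSG1, GABRP, RGS2 and UPK1B, and below for SV2B, KLHDC7B, GPNMB, SAA1 and NUPR1. The 3 genes above in the control were, nearly by definition, the 3 that were 2-fold lower in every knockdown. PADI1, a peptidylarginine deiminase gene, was at -1.35, -1.38 and -1.71 (0.19 in siIRX2 and 0.15 in siIRX4 against the other knockdowns). The neurotrophin receptor gene NGFR was at -2.06, -1.18 and -1.36, and the lysyl oxidase gene LOXL2 at -1.81, -1.13 and -2.62. The 1 gene higher in every knockdown, likewise the 1 below in the control, was ENSG00000280433, at 1.65, 1.86 and 2.12. NGFR, LOXL2 and this gene were named after their values were seen, as were MMP2, COL12A1, FANCE, MAF, CEBPB, TCHH and ALOXE3, which ran against the median of their list.

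Over the 9630 genes with a mean of at least 10 CPM, the SD of the log2 difference from the control was 0.337 in siIRX2, 0.362 in siIRX4 and 0.467 in siIRX5. Between knockdowns it was 0.364 for siIRX2 and siIRX4, 0.495 for siIRX2 and siIRX5, and 0.623 for siIRX4 and siIRX5. Set against the other knockdowns in place of the control, mitosis genes had medians of -0.34 in siIRX2, -1.34 in siIRX4 and 1.71 in siIRX5, replication genes -0.16, -0.96 and 1.08, and late differentiation genes 0.31, -0.86 and 0.48. Homologous recombination genes had medians of -0.24, -0.54 and 0.78 in that comparison. Counting noise alone gave at most 3 genes 2-fold higher or lower in any comparison, whereas the simulated library spread gave on average 144 higher and 144 lower in siIRX2, 135 and 132 in siIRX4, and 145 and 151 in siIRX5. That spread includes the differences between the knockdowns, so it gives no background rate for the observed counts. With 1 library per group, the 2-fold counts describe libraries and not conditions.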

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

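The removal of the GC and length trend and the correlation without cell cycle and repair lists were chosen after the data were seen, and the other 17 alternatives before. No paired analysis was possible because each group has 1 library, and for the same reason leaving out replicates and DESeq2 or edgeR tests were not run. Over the scalings, prior counts, thinning, mitochondrial and trend settings, the 2-fold counts stayed at 75 to 86 higher and 203 to 254 lower in siIRX2, 69 to 92 and 267 to 309 in siIRX4, and 186 to 220 and 465 to 565 in siIRX5. The mitosis median ranged over all alternatives with the control as reference from -0.998 to -0.883 in siIRX2, -1.71 to -1.55 in siIRX4 and 0.25 to 0.37 in siIRX5. List results were the same in 1230 cases, weaker in 53, stronger in 56 and reversed in 8. Of the weaker ones, 9 came with a mean of at least 20 CPM, 10 with the mean of members and 3 after thinning. Not all lists that lost a call are named above. Named genes were the same in 2311 cases, moved in 393, reversed in 32 and weaker in 1. The 2.54-fold range of depth limits transcripts with few counts.

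Counts moved with the filter and the threshold by construction, since these set how many genes can pass. Without an expression filter the 2-fold counts were 393 higher and 510 lower (siIRX2), 439 and 548 (siIRX4), and 445 and 1039 (siIRX5). Genes set apart above and below were then 302 and 183 (control), 389 and 218 (siIRX2), 310 and 138 (siIRX4), and 398 and 919 (siIRX5). Distances from the control became 0.640 (siIRX2), 0.605 (siIRX4) and 0.772 (siIRX5), and between knockdowns 0.619 for siIRX2 and siIRX4 and 0.783 for siIRX2 and siIRX5. The r of siIRX2 and siIRX5 was 0.397, and that of siIRX4 and siIRX5 reversed to 0.214 (the cause was not tested). With a mean of at least 20 CPM the 2-fold counts were 13 and 64, 6 and 104, and 84 and 146, and genes set apart were 0 and 0 (control), 3 and 11 (siIRX2), 1 and 22 (siIRX4), and 33 and 83 (siIRX5). A threshold of 1.5-fold gave 511 and 879, 637 and 688, and 1093 and 1343, and a threshold of 3-fold gave 12 and 22, 4 and 94, and 25 and 176.

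For the following values the cause was not tested. Against the mean of the other 3 libraries, 51 genes were higher and 115 lower in siIRX2, 261 higher in siIRX4 and 361 higher in siIRX5, and 6 (siIRX2) and 10 (siIRX4) lists stood apart as higher. Against the other knockdowns, 141 genes were lower in siIRX2, 425 higher in siIRX4 and 487 higher in siIRX5, with 8 lists higher and 9 lower in siIRX2 and 11 higher in siIRX4, and IRX2 in siIRX2 was at -0.90. With the mean of members, 9 lists stood apart as lower in siIRX4. Genes set apart below in the control numbered 2 with total counts, 4 with a prior count of 0.5 and 3 after thinning, which also gave 5 above. With the trend removed, r of siIRX4 and siIRX5 was -0.23 and IRX4 in siIRX4 was at -0.99.

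Ratios that changed sign were mostly small. KRT5 turned to 0.0022 in siIRX5 with median-of-ratios scaling and to -0.0187 in siIRX2 after thinning. With the trend removed, CDKN1A (0.14), IRX4 (0.21), IVL (0.21) and KRT5 (0.21) reversed in siIRX5 and KRT14 (0.0790) in siIRX2. Against the other 3 libraries, IRX4 (0.14), IVL (0.26) and KRT5 (0.20) reversed in siIRX5, IRX5 (0.29), KRT10 (0.12) and SLC2A3 (0.24) in siIRX4, and IVL (0.0096) and KRT14 (0.0143) in siIRX2, as did the base, nucleotide and mismatch repair list in siIRX2 (0.0408) and the interferon (-0.14) and hypoxia (0.10) lists in siIRX4. Against the other knockdowns, IRX4 (0.33), IVL (0.42), KRT5 (0.30) and CHORDC1 (-0.0097) reversed in siIRX5; IRX5 (0.60), KRT10 (0.28), PADI1 (0.15), SLC2A3 (0.66), CMPK2 (-0.22) and SKIL (-0.17) in siIRX4; and CDC45 (0.0422), IVL (0.14), KRT14 (0.0650), KRT4 (0.36), PADI1 (0.19), RPS15 (0.0614) and S100A8 (0.29) in siIRX2. The lists that reversed there were base, nucleotide and mismatch repair (0.0477), wound (0.18) and ribosomal proteins (0.0432) in siIRX2, and interferon (-0.29) and hypoxia (0.21) in siIRX4.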

Other observations

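Of the markers of other cell types that a keratinocyte culture could hold, too few members were measured for a median. Of the fibroblast list, 4 of 16 genes were measured: COL1A1 was at 14.3, 15.7, 14.5 and 13.3 CPM in control, siIRX2, siIRX4 and siIRX5, FBLN1 at 68.6, 30.6, 35.4 and 56.6 CPM, TWIST2 at 8.03, 3.28, 7.78 and 5.35 CPM, and LOX at 2.43, 1.22, 4.75 and 3.02 CPM. Of the melanocyte list, 4 of 14 were measured: PMEL was at 1.62, 1.73, 2.27 and 2.58 CPM, MITF at 3.50, 5.01, 4.53 and 5.79, GPR143 at 2.59, 2.67, 3.64 and 0.755, and QPCT at 15.5, 9.41, 17.2 and 10.7. CD74, at 5.61, 5.76, 7.76 and 4.85 CPM, was the 1 measured gene of 14 immune and endothelial markers.

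The log2 ratios were lower for genes rich in G and C bases in every comparison, with r across genes of -0.204 (siIRX2), -0.193 (siIRX4) and -0.353 (siIRX5). In siIRX5 the genes in the lowest 20% of GC content had a median of 0.30 and those in the highest 20% -0.24. Of the 543 genes 2-fold lower in siIRX5, 409 were also called after the trend was removed, as were 130 of the 205 higher genes.

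In the tests below, removal of the GC and length trend and the r without cell cycle and repair lists were added after the data were seen, with their bounds written before their results. The reference of the other knockdowns was planned, but its use as a test of an unusual control was chosen after its result was seen. Bootstrap intervals over list members or genes describe these libraries and not replicate cultures.

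The first pattern is the lower level of mitosis genes in siIRX2 and siIRX4. A trend with GC content and transcript length as the whole cause is argued against, since the list median was -0.998 (interval -1.08 to -0.91) in siIRX2 and -1.71 (-1.85 to -1.62) in siIRX4 once the trend was removed. After thinning the siIRX4 median was -1.68 (-1.82 to -1.59). Thinning leaves the expected ratios unchanged, so it could not decide on the greater depth of siIRX4. An unusual control library as the whole cause is argued against for siIRX4 by a median of -1.34 (-1.38 to -1.22) against the other knockdowns. That reference averages siIRX2, at -0.98 against the control, with siIRX5, at 0.36, so the gap rests more on siIRX5 than on siIRX2. An unusual control stays open for siIRX2, which lay between the other knockdowns with a median of -0.34 (-0.38 to -0.25) against them. The density or growth state of single wells stays open for both siIRX2 and siIRX4, because the number of libraries per siRNA is 1. A hypothesis is that IRX4 knockdown may lower mitosis genes, which these data cannot separate from the state of single wells.

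The second pattern is the lower level of amino acid stress and NRF2 genes in siIRX5. With the trend removed the amino acid stress median was -0.58 (-0.96 to -0.45), which argues against the trend as the whole cause. Against the other knockdowns it was -0.53 (-0.79 to -0.41), with its upper end close to the bound of -0.4. That reference averages siIRX4, at 0.07 against the control, with siIRX2, at -0.51 with 38 of 40 members below the control. An unusual control as the whole cause is therefore argued against mainly through siIRX4, and the list was lower in siIRX2 as well. For the NRF2 list the values were -0.51 (-1.02 to -0.11) and -0.62 (-1.20 to -0.37). Neither interval cleared the bound of -0.4, which was set before the result for the trend alone, so the trend stays open for that list. Against the control, its medians in siIRX2 (-0.05) and siIRX4 (0.12) did not stand apart, and 24 of 28 members were lower in siIRX5 than in the other knockdowns. These values argue against an unusual control as the whole cause for that list. Medium or nutrient state of single wells cannot be told apart from the knockdown, since there is 1 library per siRNA. A hypothesis is that IRX5 knockdown may lower amino acid stress genes, and it stays untested against well-to-well spread, while heat shock genes had a median of 0.23 in siIRX5.

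The third pattern is the opposite direction of siIRX4 and siIRX5. The trend with GC content ran the same way in siIRX4 (r -0.193) and siIRX5 (-0.353), as did that with transcript length (0.213 and 0.174). A shared direction raises r, so removing the trend could not test the negative sign. The r across genes was then -0.23 (-0.25 to -0.21). Without the 202 members of the cell cycle and repair lists r was -0.10 (-0.12 to -0.07). Those lists alone therefore do not account for the negative sign among genes past the expression filter. These intervals treat genes as independent, which they are not, and are too narrow. The sign turned without the expression filter (0.214), where genes with few counts may add the control's shared noise; that cause was not tested. No biological explanation was tested, because a difference between single wells would give the same pattern.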
